A study of Caenorhabditis elegans with 32 samples.

How the data were processed

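Whole worms of 2 C. elegans strains were sampled at 5 times around a heat shock, in 32 libraries that form 10 groups. Per the labels, strain JR3642 carried heat-shock elt-7 with an elt-2 promoter GFP reporter and an IFB-2 fusion to CFP, and strain CL2070 served as control. Worms grew at 20 C on bacteria, and each culture held about 2000 synchronized animals, heated at 33 C for 30 min as early L4 larvae. Total RNA was extracted with TriReagent and column purification, and libraries were made with a stranded mRNA kit that selects polyadenylated RNA. The labels number the replicates within each strain and time, but do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be partly technical.

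Each deposited sample file gives, per the file headers, the length, effective length, TPM and estimated read number of each gene. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36.3 and assigned to transcripts with Salmon 0.8.2; the genome build and annotation are not given in the sources used here. The estimated counts, per the file headers, are not normalized, and 85.9% to 91.6% of the values in a library were whole within 1e-06. The deposited TPM values are shares of 1e6 transcripts and carry no depth. A deposited table of TPM values of the whole series was compared with the sample files, and differed by at most 4.4e-08. In 24 libraries the effective length is the length less 200.43 bases for long genes, whereas the 8 libraries of 3 h carry values of their own, 164.8 to 171.9, so they were quantified with other settings or fragment lengths than the rest. All comparisons that involve 3 h set libraries with different length corrections against each other. Within 3 h they were 164.8 to 168.7 in the elt-7 strain and 169.2 to 171.9 in the control strain.

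Gene identifiers were matched to the WBcel235 annotation of release 115, used for symbols and coordinates: 19980 of 20094 identifiers were found and 19736 had a symbol. Salmon divides reads among similar transcripts by an estimate, so genes with near-identical copies are uncertain. Estimated counts were rounded to whole numbers, and genes with too few reads were removed by filterByExpr with the groups, which left 18640 genes holding 99.99% of reads. Library sizes were scaled with TMM. All 32 libraries were fitted in 1 quasi-likelihood model with a mean per group (edgeR 4.0.16, robust dispersion, R 4.3.3). From it came the strain difference at each time (elt-7 strain minus control strain), the strain-by-time difference at 3, 6, 12 and 30 h (the strain difference at that time minus the one at 0 h) and the change of the control strain from 0 h. A higher strain-by-time difference need not be a rise in the elt-7 strain, since a smaller fall also gives one. Likewise a lower one need not be a fall, since a smaller rise also gives one. Every adjusted p for a gene is from edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Levels are counts per 1e6 reads (CPM) on TMM-scaled library sizes, as mean ± SD over replicates. The log2 CPM values behind the correlations between libraries and between strains use a prior count of 2. Fitted log2 differences use edgeR's default prior count instead. Where a group had no reads, the fold is a lower bound against 3 counts over the group, which covers counting error only.

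Before the data were examined, 28 gene lists for tissues, developmental programmes and stress responses were written from general knowledge, from which elt-7, ifb-2 and rol-6 were left out as transgenes. The gene elt-2, whose promoter drives the reporter, was kept in its list. Each list was tested in the strain-by-time differences, the strain difference at 0 h and the control changes with camera in limma 3.58.1 (preset correlation 0.01), beside camera with an estimated correlation and fry. Adjustment was by Benjamini-Hochberg over the lists and times of one kind of comparison. The count of called members adjusted over the list alone stands beside each count. The genes named in the text follow a rule fixed at the same time. It takes the 5 target genes. For each strain-by-time difference it takes the 10 highest and 10 lowest log2 values among genes called in it and in the strain difference, of the same sign, with at least 5 CPM on average and no overlap between the strains' replicates. It adds up to 4 members per list and time with the lowest p, and the 5 highest and 5 lowest values at 0 h and for each control change. Not every gene the rule admits is named. Genes outside this rule were chosen after their values were seen: the copies pud-1.2 and hsp-16.1 (WBGene00002017), and those of the closing section.

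The alternatives were DESeq2 1.42.0, RLE and upper-quartile size factors, other filters, a fold threshold, an effective length offset, limma-trend on log2(TPM + 1), a fit of only the groups compared, the replicate number as a block and leaving out each replicate in turn. The 36 pairs of replicates differed by 5 to 150 times sampling noise (chi-square per degree of freedom), with correlations of 0.886 to 0.997, so no library appeared to be a copy of another. The procedure was tested on simulated counts with known changes: for the strain difference at 6 h it recovered 42%, 70%, 96% and 98% of genes changed 1.5-, 2-, 4- and 8-fold, with 2.5% false calls. For the strain-by-time difference at 6 h the shares were 16%, 46%, 88% and 98%, with 3.1% false calls, over 18116 genes in both cases. In the simulation 50 genes changed at each fold, equally up and down, in the elt-7 strain at 6 h only. They were drawn above a minimum level, and the spread was taken from the fitted model. The real comparisons called a larger share of genes, some with no reads in a group, so recovery and false calls may differ there.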

Results

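The series followed gene expression in whole Caenorhabditis elegans after a heat shock that switched on the transcription factor ELT-7 throughout the body. ELT-7 is a GATA factor that normally acts in the intestine, where it works with ELT-2 to specify and maintain gut cells. Forced ELT-7 is known as a tool for turning pharynx and gonad cells towards a gut-like fate, and the series title places the work in that setting of cellular reprogramming. The elt-7 strain carried elt-7 under a heat-shock promoter together with a fluorescent elt-2 reporter and a fluorescent fusion of the intestinal intermediate filament IFB-2. The control strain carried GFP under a heat-shock promoter and rol-6 as a marker. Cultures of about 2000 synchronized worms were heated at 33 C for 30 min at the early L4 larval stage. RNA was taken before the heat shock (0 h) and 3, 6, 12 and 30 h after it, which in unperturbed worms spans the last larval moult and the onset of egg production. Each strain had 4 libraries at 3 h and 3 at each of the other times, 32 libraries in all, with 16 to 69.4 estimated reads x 1e6 per library. The 8 libraries of 3 h held 16.3 to 19.5 x 1e6 reads each. Of 20094 genes, 18640 had enough reads to be tested.

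The induced gene and the transgenic genes were measured first, since elt-7 checks the strain labels. All coordinates are from the WBcel235 assembly, and all 5 genes are annotated as protein coding. Transcripts of elt-7 (WBGene00015981, chromosome V, 4770670 to 4773086, plus strand) stood at 126 ± 3.7 counts per 1e6 reads (CPM, mean ± SD, n = 3) in the elt-7 strain before heat shock and 13 ± 0.83 (n = 3) in the control strain. They stood at 1120 ± 1030 at 3 h (n = 4), 1240 ± 173 at 6 h, 1670 ± 79.1 at 12 h and 347 ± 21.5 at 30 h, against 12.9 to 20.2 CPM on average in the control strain. The strain difference for elt-7 was 3.29 on the log2 scale at 0 h (SE 0.4, edgeR adjusted p = 6.65e-06) and 7.02 at 12 h (SE 0.47, adjusted p = 2.01e-12). Relative to 0 h, the difference was called at 3 h (2.79, adjusted p = 6.1e-05), 6 h (2.85, 6.98e-05) and 12 h (3.74, 2.79e-06), and at 30 h it was 0.81 (adjusted p = 0.179). The wide spread at 3 h came from replicate 3, at 2650 CPM against 449 to 702 in the other 3 libraries. These reads cannot be divided between the native gene and the transgene.

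The gut factor elt-2 (WBGene00001250, chromosome X, 10481240 to 10483441, plus strand), a known target of ELT-7, stood at 45.8 ± 1.89 CPM at 0 h and 231 ± 46.6 at 3 h in the elt-7 strain and was 95.1 ± 21.6, 97.4 ± 4.94 and 52.5 ± 2.77 at 6, 12 and 30 h. In the control strain it lay between 13.6 and 23.2 CPM on average. The labels name an elt-2 promoter reporter in the elt-7 strain, without saying whether it carries transcribed elt-2 sequence. Reads of elt-2 need not all come from the native gene. Relative to 0 h, elt-2 was higher in the elt-7 strain by 2.17 (log2) at 3 h (SE 0.24, adjusted p = 5.67e-08) and by 0.80 at 30 h (SE 0.25, adjusted p = 0.00722). The intermediate filament gene ifb-2 (WBGene00002054, chromosome II, 5750188 to 5754140, plus strand) reached 3470 ± 893 CPM at 3 h against 441 ± 70.4 in the control strain. The IFB-2 fusion of the elt-7 strain carries ifb-2 sequence, and its reads were not separated from those of the native gene. The small heat-shock gene hsp-16.2 (WBGene00002016, chromosome V, 1804334 to 1804957, minus strand) rose in the control strain from 14.1 ± 1.04 CPM to 118 ± 22.7 at 3 h and stood at 9.47 ± 1.55 at 12 h. In the elt-7 strain it stood at 382 ± 209 at 3 h, 268 ± 9.66 at 6 h and 24.4 ± 2.1 at 30 h. The strain-by-time difference for hsp-16.2 was 1.18 at 3 h (adjusted p = 0.0171) and 3.65 at 12 h (adjusted p = 1.95e-07). At 3 h that call was lost without replicate 3 of the elt-7 strain at 0 h (adjusted p = 0.0503, the highest over the alternatives, which ranged from 0.0035). The cuticle collagen gene rol-6 (WBGene00004397, chromosome II, 8733050 to 8734239, plus strand) is the marker of the control strain, but its levels do not separate the strains as the labels would have it. It stood at 1320 ± 198 CPM in the elt-7 strain at 0 h against 396 ± 59.6 in the control strain. Only at 6 h was the control strain higher, at 787 ± 24 against 508 ± 30.4. At 30 h the elt-7 strain had 1940 ± 407 and the control strain 44.4 ± 7.34.

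**Figure D1:**
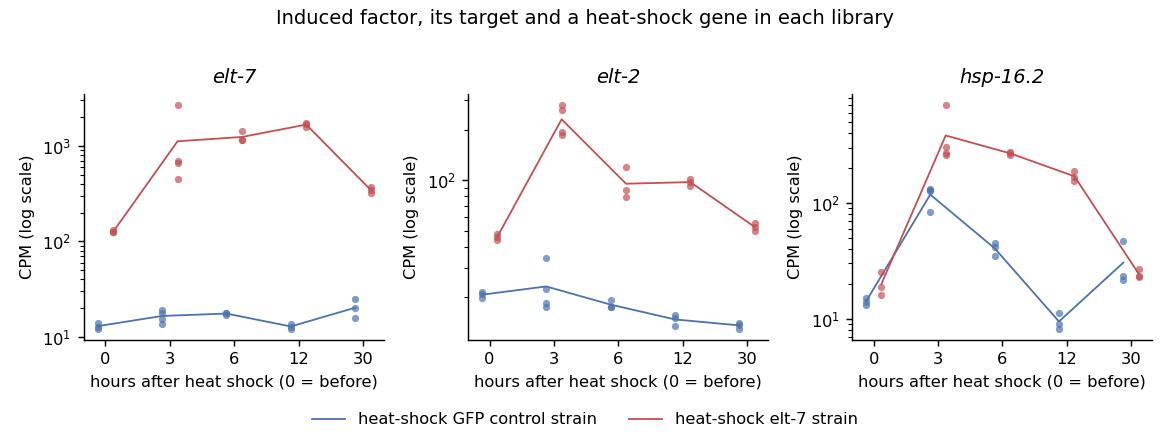
Levels of elt-7, elt-2 and hsp-16.2 in CPM (log axis) against hours after heat shock, with 1 point per library and lines through the group means of the elt-7 strain (red) and the control strain (blue). Transcripts of elt-7 averaged 1120 to 1670 CPM from 3 to 12 h in the elt-7 strain and stayed under 25 CPM in every control library.

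Before heat shock the strains already differed. Of 20 genes of the intracellular pathogen response, a set induced by microsporidia and viruses in the gut, 7 were higher in the elt-7 strain (8 adjusted over the list alone), with a median log2 difference of 0.82. The camera call of that list (adjusted p = 1.63e-10) was lost with an estimated correlation (adjusted p = 0.867 with an estimated correlation). C17H11.2 stood at 11.5 ± 0.263 CPM in the elt-7 strain and had no reads in the control strain, at least 195-fold higher, taking 3 counts over the group as the floor. C39B10.7 was at 67.7 ± 6.06 against 1.58 ± 0.203 CPM and F57G4.11 at 5.11 ± 2.08 against 0.0735 ± 0.0648. C39B10.7 (chromosome X, 10476873 to 10477891, plus strand) lies upstream of elt-2, and the labels do not say how much of that region the elt-2 reporter carries. Lower in the elt-7 strain were Y73B3A.1 (0.12 ± 0.0961 against 18 ± 3.4), BE0003N10.6 (1.95 ± 0.237 against 18 ± 2.86), the lipase-like gene lips-6 (3.38 ± 2.13 against 26.4 ± 18.3), K01D12.9 (7.62 ± 2.38 against 45.5 ± 9.36) and the collagen gene col-156 (31.6 ± 2.28 against 164 ± 7.04, all n = 3). For col-156 the call (adjusted p = 0.015) was lost without any 1 of the 3 elt-7 libraries of 0 h, at adjusted p of 0.0764, 0.0604 and 0.0576 without replicates 1, 2 and 3 (range over all alternatives 4.16e-08 to 0.0764). Of the pharyngeal cuticle list, 3 of 20 genes were lower (1 higher and 6 lower adjusted over the list alone).

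In all, 667 genes were higher and 220 lower in the elt-7 strain at 0 h. This count depended on the fit: it was 2220 without the 3 h libraries and 2884 with only the 6 libraries compared. It was 449 and 486 without replicates 1 and 2 of the elt-7 strain, and 456 and 400 without replicates 1 and 3 of the control strain. Of the calls, 75.2% were higher, against 63.2% with median-of-ratios (RLE) size factors, 60.5% with upper-quartile factors, 62.1% with DESeq2 and 49.8% in the fit of the 6 libraries alone.

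The control strain shows what heat shock and the passage from L4 to adulthood did without heat-shock elt-7. In the first 6 h the genes for oocyte proteins rose, with 23 of 24 tested genes higher at 3 h and 22 at 6 h (23 and 22 adjusted over the list alone). The median log2 change was 1.15 at 3 h and 1.43 at 6 h. The camera calls, at adjusted p = 9.89e-12 and 1.91e-19, did not hold with an estimated correlation (adjusted p = 0.340 and 0.192 with an estimated correlation). All 31 genes for major sperm proteins, the main cytoskeletal proteins of nematode sperm, were higher at 6 h (31 adjusted over the list alone, median 2.18, camera adjusted p = 7.2e-17, and adjusted p = 0.277 with an estimated correlation). Of 28 other sperm genes, 19 were higher (19 adjusted over the list alone, camera adjusted p = 4.08e-08, and adjusted p = 0.426 with an estimated correlation). Ribosomal protein genes were lower at 3 h, 74 of 78, by a median of -0.72 (75 adjusted over the list alone, camera adjusted p = 3.21e-54, and adjusted p = 0.0649 with an estimated correlation). In the mitochondrial unfolded protein response, 9 of 14 genes were lower at 3 h (10 adjusted over the list alone, median -0.58), and this list kept its call (adjusted p = 2.14e-07, and adjusted p = 0.0391 with an estimated correlation). Body wall muscle genes were lower at 3 h in 22 of 27 cases (24 adjusted over the list alone, median -0.83, adjusted p = 4.37e-14, and adjusted p = 0.124 with an estimated correlation). The heat shock list was split, with 7 of 24 genes higher and 10 lower at 3 h (7 and 10 adjusted over the list alone); its median of -0.13 turned to 0.23 on the TPM scale.

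The yolk protein precursors led the later change in the control strain. Of the 6 vitellogenin genes, 5 were higher at 6 h and all 6 at 12 and 30 h (5, 6 and 6 adjusted over the list alone), with medians of 4.24, 7.53 and 8.2. Their camera calls had adjusted p = 2.75e-06, 7.39e-05 and 0.0176, and adjusted p = 0.149, 0.232 and 0.463 with an estimated correlation. Y57G11B.5 had no reads at 0 h in the control strain and reached 144 ± 23.4 CPM at 12 h and 241 ± 4.02 at 30 h, at least 2440-fold and 4100-fold higher. ZK813.3 was likewise at 0 before heat shock and at 262 ± 9.33 CPM at 30 h, at least 4440-fold higher. Y62H9A.3 rose from 0 to 82.4 ± 4.46 CPM at 12 h, at least 1400-fold. The moulting genes fell: 23 of 25 were lower at 12 h and all 25 at 30 h (23 and 25 adjusted over the list alone), with medians of -3.54 and -3.48. Their camera calls had adjusted p = 1.89e-19 and 2.09e-09, and adjusted p = 0.0641 and 0.192 with an estimated correlation. Among them, fbn-1, an apical matrix gene, went from 385 ± 35 CPM at 0 h to 4.77 ± 1.25 at 12 h, and the hedgehog-related wrt-10 from 335 ± 2.02 to 4.94 ± 1.39. The collagen gene col-41 went from 192 ± 26.1 CPM at 0 h to 22.2 ± 17.6 at 6 h and 0.249 ± 0.271 at 30 h, and col-169 from 577 ± 64.6 to 0.855 ± 0.617 at 30 h. The secreted-protein gene grd-13 stood at 14.3 ± 8.45 CPM at 6 h against 130 ± 22.6 at 0 h.

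By 30 h all 28 replication and cell-cycle genes were higher in the control strain than at 0 h (28 adjusted over the list alone, median 2.09), and all 24 oocyte genes (24 adjusted over the list alone, median 5.31). Those camera calls had adjusted p = 1.41e-21 and 1.33e-16, and adjusted p = 0.125 and 0.243 with an estimated correlation. Genes first transcribed in embryos were higher in 17 of 20 cases and lower in 2 (17 and 3 adjusted over the list alone). Their median was 5.46, or 4.13 with groups at 0 set to 3 counts, and the list kept its call (adjusted p = 0.000177, and adjusted p = 0.0391 with an estimated correlation). All 31 major sperm protein genes and 27 of 28 other sperm genes were lower (31 and 27 adjusted over the list alone), with medians of -3.39 and -3.63. Their calls had adjusted p = 2.71e-05 and 1.45e-06, and adjusted p = 0.590 and 0.495 with an estimated correlation. Over all genes, 4023 were higher and 3737 lower at 3 h, 3613 and 2699 at 6 h, 4925 and 6074 at 12 h, and 6554 and 7341 at 30 h.

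Several of the lowest values of the control strain at 3 h are uncertain. The genes pud-1.1, hsp-16.1 (WBGene00002015), nola-3, msd-1 (WBGene00009684) and Y19D2B.1 had no reads in the 4 control libraries of 3 h, against 203 ± 48.7, 81.1 ± 7.48, 33.1 ± 4.85, 28.8 ± 5.44 and 19.6 ± 2.73 CPM at 0 h. Those floors make them at least 5740-fold, 2280-fold, 933-fold, 810-fold and 554-fold lower. The 3 h libraries also carry a different length correction, and the copies pud-1.2 and hsp-16.1 (WBGene00002017) were at 823 and 217 CPM at 3 h. Of the calls at 3 h, 51.8% were higher, against 87.1% on the TPM scale, which moved the median of all genes from 0.06 to 0.34. At 30 h 47.2% were higher, against 36.5% with upper-quartile factors, which moved that median from -0.10 to -0.49; at 12 h they moved it from -0.12 to -0.30. For hsp-16.2 the rise at 30 h (log2 1.11, adjusted p = 0.002) was lost without replicate 1 of the control strain at 30 h (adjusted p = 0.104, range over all alternatives 0.000106 to 0.104).

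At 3 h, relative to the control strain and to 0 h, the elt-7 strain had switched on genes that were near the detection limit in the control strain. The F-box gene fbxb-96 stood at 133 ± 52.6 CPM (n = 4) and fbxc-29 at 37.1 ± 0.471, with no reads in the 4 control libraries, at least 3740-fold and 1050-fold higher. The C-type lectin gene clec-45 stood at 966 ± 416 CPM against 0.499 ± 0.11, a log2 strain-by-time difference of 11.46 (SE 0.97, adjusted p = 7.59e-10). With 1 read each in the control libraries of 3 h, fbxa-28 was at 155 ± 127 CPM, W07G4.1 at 97.4 ± 13.7 and clec-121 at 60.7 ± 20.4. The calls for fbxb-96, fbxc-29 and clec-121 ended without replicate 1 of the control strain at 0 h and that for W07G4.1 without its replicate 2, each with adjusted p = 1, while the log2 differences stayed at 11.40, 9.82, 8.02 and 10.12. Over all alternatives their lowest adjusted p were 3.16e-17, 1.46e-20, 5.68e-17 and 1.28e-18.

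The pathogen response and immune lists moved upward at 3 h. Of the 20 intracellular pathogen response genes, 10 were higher and 2 lower (10 and 2 adjusted over the list alone). The median log2 difference was 2.72. F26F2.1 stood at 427 ± 190 CPM against 0.68 ± 0.118, F26F2.3 at 273 ± 99.3 against 0.167 ± 0.0676 and pals-1 at 36.9 ± 16.8 against 1.87 ± 0.578. The ubiquitin ligase component gene skr-4 was lower, at 13.5 ± 4.72 against 39.6 ± 3.7. The list's call (camera adjusted p = 0.000601) did not hold with an estimated correlation (adjusted p = 0.546 with an estimated correlation). Of 33 innate immune effectors, 16 were higher and 4 lower (16 and 4 adjusted over the list alone, camera adjusted p = 0.00607, and adjusted p = 0.619 with an estimated correlation). The antimicrobial peptide genes cnc-2 and nlp-31 stood at 179 ± 29.3 and 662 ± 207 CPM against 2.33 ± 1.11 and 81.2 ± 25.5, the lectin clec-60 at 296 ± 74.2 against 5.89 ± 2.95, and clec-7 was lower, at 0.844 ± 0.37 against 25.1 ± 7.64. Of 35 oxidative stress and detoxification genes, 15 were higher and 6 lower (15 and 6 adjusted over the list alone, camera adjusted p = 0.0236, and adjusted p = 0.522 with an estimated correlation). The cytochrome P450 gene cyp-35A3 stood at 315 ± 117 against 11.9 ± 4.12 CPM. Heat shock genes were higher in 12 of 24 cases and lower in 2 (12 and 2 adjusted over the list alone, camera adjusted p = 0.037, and adjusted p = 0.619 with an estimated correlation). Ribosomal protein genes, 68 of 78, were higher by a median of 0.42 (72 adjusted over the list alone, camera adjusted p = 1.04e-08, and adjusted p = 0.546 with an estimated correlation); rpl-3 was at 5070 ± 152 against 3970 ± 307 CPM and rpl-33 at 1200 ± 49.2 against 884 ± 56.4.

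The gut lists went in both directions at 3 h. Of the 5 tested endoderm GATA factors and inducers, elt-2 and elt-4 were higher (2 adjusted over the list alone), elt-4 at 4.36 ± 0.797 against 1.39 ± 0.169 CPM; the list itself had camera adjusted p = 0.0728. Transporter and metal genes were higher in 10 of 20 cases and lower in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0275, and adjusted p = 0.463 with an estimated correlation). The transporter gene pgp-1 stood at 143 ± 15.2 against 9.61 ± 5.67 CPM and the cadmium-responsive cdr-1 at 56.4 ± 22.6 against 2.21 ± 1.27. The gut peptide transporter gene pept-1 was lower, at 17.4 ± 4.8 against 218 ± 57.8. In the brush border list 6 of 11 genes were lower (6 adjusted over the list alone, camera adjusted p = 0.000414, and adjusted p = 0.411 with an estimated correlation). The intermediate filament gene ifc-1 stood at 7.95 ± 3.42 against 78.4 ± 23.7 CPM and erm-1 at 175 ± 5.93 against 322 ± 15.6. Of 32 digestive enzyme genes, 6 were higher and 18 lower (6 and 18 adjusted over the list alone, camera adjusted p = 0.142): the lysozyme gene lys-1 was at 6400 ± 612 against 558 ± 101 CPM. In lipid synthesis 3 of 18 genes were higher and 5 lower (3 and 5 adjusted over the list alone), a balance that turned to 5 higher and 3 lower with RLE size factors; dgat-2 was at 270 ± 109 against 19.9 ± 3.33 CPM and the fatty acid elongase gene elo-6 at 18.8 ± 2.79 against 250 ± 59.6.

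In the lists of moulting, oocytes, muscle, pharynx, neurons and somatic gonad, more genes were called lower than higher at 3 h. Of 25 moulting genes, 20 were lower and 1 higher (21 and 1 adjusted over the list alone, median -1.42, camera adjusted p = 4.84e-05, and adjusted p = 0.444 with an estimated correlation). Oocyte genes were lower in 22 of 24 cases (22 adjusted over the list alone, median -1.15, camera adjusted p = 0.000615, and adjusted p = 0.631 with an estimated correlation). The eggshell gene perm-4 stood at 4.92 ± 3.44 against 50 ± 28.6 CPM and cpg-2 at 37.7 ± 15.8 against 129 ± 51.5. Of 27 body wall muscle genes, 13 were lower and 1 higher (13 and 1 adjusted over the list alone, camera adjusted p = 0.00467, and adjusted p = 0.619 with an estimated correlation). The muscle regulator gene hlh-1 stood at 0.463 ± 0.202 against 5.38 ± 1.26 CPM and unc-112 at 51.2 ± 5.61 against 126 ± 8.15. The titin-like ttn-1 was higher, at 665 ± 128 against 121 ± 24.9. Pharyngeal muscle genes were lower in 10 of 18 cases and higher in 1 (12 and 1 adjusted over the list alone, camera adjusted p = 0.00591, and adjusted p = 0.444 with an estimated correlation). The homeobox gene ceh-34 stood at 0.548 ± 0.278 against 6.71 ± 0.771 CPM. Pharyngeal gland genes were lower in 6 of 11 cases and higher in 1 (6 and 1 adjusted over the list alone, camera adjusted p = 0.223); the higher one was phat-1, at 91.9 ± 59.3 against 7.36 ± 1.69 CPM. Of 25 neuronal genes, 11 were lower and 4 higher (11 and 4 adjusted over the list alone, camera adjusted p = 0.0299, and adjusted p = 0.631 with an estimated correlation). The GABA synthesis gene unc-25 stood at 7.03 ± 1.94 against 30.5 ± 3.09 CPM; unc-119, at 1090 ± 110 against 12.4 ± 1.32, is also a common transformation marker, and the labels do not say whether a transgene carries it. Of 20 gonad and vulva genes, 11 were lower and 4 higher (11 and 4 adjusted over the list alone, camera adjusted p = 0.274). The member fkh-6 stood at 3.72 ± 0.466 against 12.1 ± 0.908 CPM.

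Sperm and cuticle lists also held more lower than higher genes at 3 h. Major sperm protein genes were lower in 24 of 31 cases and higher in 1 (27 and 1 adjusted over the list alone, median -1.60, camera adjusted p = 0.00439, and adjusted p = 0.687 with an estimated correlation). Of 36 cuticle collagens, 19 were lower and 3 higher (21 and 3 adjusted over the list alone, camera adjusted p = 0.0757). Pharyngeal cuticle genes were lower in 12 of 20 cases and higher in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.631 with an estimated correlation). Of all genes, 3894 were higher and 4573 lower at 3 h. The share of higher calls was 46.0%, against 57.9% with DESeq2 and 34% on the TPM scale, which moved the median of all genes from -0.03 to -0.25.

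At 6 h the intracellular pathogen response led the genes that were higher in the elt-7 strain. Of its 20 genes, 17 were higher (17 adjusted over the list alone), with a median log2 difference of 6.94. F26F2.1 reached 2650 ± 469 CPM (n = 3) against 1.29 ± 0.143, the cullin gene cul-6 360 ± 32.6 against 7.73 ± 0.812, skr-4 664 ± 15.4 against 24.8 ± 2.3 and pals-1 134 ± 24.2 against 1.18 ± 0.392. The camera call (adjusted p = 3.97e-17) did not hold with an estimated correlation (adjusted p = 0.203 with an estimated correlation). Outside the list, pals-28 stood at 766 ± 90.1 against 0.0427 ± 0.0171 CPM, pals-8 at 144 ± 14.8 against 0.0446 ± 0.00981, Y71H2AR.2 at 437 ± 101 against 0.0427 ± 0.0171 and rabr-4 at 325 ± 101 against 0.0233 ± 0.0202. At 126 ± 4.46 CPM against no reads, clec-121 was at least 6640-fold higher. Without replicate 2 of the control strain at 0 h the call for pals-28 was lost (adjusted p = 0.0891, range over all alternatives 9.59e-27 to 0.0891). Without its replicate 1 those for rabr-4 (adjusted p = 0.0807, range 7.11e-22 to 0.0807) and clec-121 (adjusted p = 1, range 2.49e-17 to 1) were lost. The log2 differences in those fits were 12.85, 13.76 and 11.33.

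More chaperone and autophagy genes were called higher than lower at 6 h. Heat shock genes were higher in 19 of 24 cases and lower in 2 (20 and 3 adjusted over the list alone, median 2.1, camera adjusted p = 3.72e-09, and adjusted p = 0.203 with an estimated correlation). The small heat-shock gene hsp-16.1 (WBGene00002015), one of a pair of near-identical copies, stood at 1430 ± 13.3 against 86.4 ± 8.5 CPM, hsp-90 at 6150 ± 275 against 2260 ± 55.2, dnj-13 at 1460 ± 172 against 289 ± 17.3 and hsp-110 at 1640 ± 110 against 418 ± 30.7. Of 32 autophagy and lysosome genes, 16 were higher and 1 lower (16 and 1 adjusted over the list alone, camera adjusted p = 0.000174, and adjusted p = 0.498 with an estimated correlation). The member atg-18 stood at 816 ± 83.2 against 131 ± 4.46 CPM and the beclin gene bec-1 at 141 ± 3.46 against 38.8 ± 2.49. In the endoplasmic reticulum unfolded protein response 11 of 20 genes were higher and 3 lower (12 and 3 adjusted over the list alone, camera adjusted p = 0.0202, and adjusted p = 0.619 with an estimated correlation). The BiP gene hsp-4 stood at 1460 ± 87 against 512 ± 13.6 CPM and its sensor gene ire-1 at 182 ± 3 against 96.2 ± 1.63. The glutathione transferase gene gst-30 stood at 18.6 ± 1.4 against 0.324 ± 0.0196 CPM and dhs-8 at 154 ± 66.9 against 0.647 ± 0.269.

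The cuticle programme was lower at 6 h, when the control strain expressed it at a high level. Of 25 moulting genes, 20 were lower and 1 higher (21 and 1 adjusted over the list alone, median -2.89, camera adjusted p = 4.85e-12, and adjusted p = 0.203 with an estimated correlation). The member qua-1 stood at 39.9 ± 8.28 against 627 ± 59.9 CPM and the period-like timing gene lin-42 at 21.6 ± 4.44 against 289 ± 29.1. Of 36 cuticle collagens, 27 were lower and 2 higher (28 and 2 adjusted over the list alone, camera adjusted p = 0.000116, and adjusted p = 0.498 with an estimated correlation). The difference was -6.38 (log2) for the collagen gene bli-1 and -4.43 for dpy-8. The member dpy-14 was higher, at 101 ± 16.7 against 0.323 ± 0.2 CPM. Pharyngeal cuticle genes were lower in 17 of 20 cases (17 adjusted over the list alone, median -3.70, or -3.53 with groups at 0 set to 3 counts, camera adjusted p = 6.09e-06, and adjusted p = 0.436 with an estimated correlation). The member abu-13 stood at 35 ± 8.12 against 296 ± 6.74 CPM. Body wall muscle genes were lower in 25 of 27 cases and higher in 1 (25 and 1 adjusted over the list alone, median -1.37, camera adjusted p = 3.05e-10, and adjusted p = 0.267 with an estimated correlation). The integrin gene pat-2 stood at 38 ± 3.99 against 204 ± 3.93 CPM. Pharyngeal muscle genes were lower in 15 of 18 cases and higher in 2 (16 and 2 adjusted over the list alone, camera adjusted p = 2.68e-06, and adjusted p = 0.203 with an estimated correlation). The member nep-1 stood at 58.3 ± 1.92 against 197 ± 10.7 CPM and marg-1 at 1.33 ± 0.246 against 11 ± 0.73.

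In the yolk, lipid and digestive lists more genes were called lower than higher at 6 h. Of the 6 vitellogenin genes, 4 were lower (4 adjusted over the list alone, camera adjusted p = 0.105). The member vit-6 stood at 19.5 ± 3.13 against 2000 ± 609 CPM and vit-2 at 29.4 ± 5.08 against 1150 ± 459. In lipid synthesis 12 of 18 genes were lower and 1 higher (12 and 2 adjusted over the list alone, camera adjusted p = 0.00793, and adjusted p = 0.435 with an estimated correlation). The member elo-6 stood at 4.96 ± 0.686 against 303 ± 49.5 CPM and the desaturase gene fat-6 at 21.7 ± 5.03 against 617 ± 50.5. Of 32 digestive enzyme genes, 21 were lower and 3 higher (21 and 3 adjusted over the list alone, camera adjusted p = 0.000615, and adjusted p = 0.435 with an estimated correlation). The aspartyl protease gene asp-13 stood at 25.8 ± 4.76 against 422 ± 36.2 CPM. In the brush border list ifp-1 was at 4.6 ± 0.557 against 73.9 ± 5.48 CPM and ifd-1 at 190 ± 6.43 against 57.6 ± 1.47. In all, 4360 genes were higher and 4703 lower at 6 h. No call of a list with at least 5 tested genes held with an estimated correlation at 3, 6, 12 or 30 h.

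At 12 h oocyte, cell-cycle and muscle genes were lower in the elt-7 strain. From 0 h the oocyte and cell-cycle lists rose in the control strain by medians of 4.46 and 1.41, so their lower differences need not be a fall. All 24 oocyte genes were lower (24 adjusted over the list alone), by a median of -3.32, at camera adjusted p = 3.23e-24 (adjusted p = 0.210 with an estimated correlation). The chitin synthase gene chs-1, needed for the eggshell, stood at 21.9 ± 3.67 against 248 ± 22.2 CPM, and spn-4 at 61 ± 8.53 against 442 ± 19.6. All 28 replication and cell-cycle genes were lower (28 adjusted over the list alone, median -1.32, camera adjusted p = 1.51e-18, and adjusted p = 0.224 with an estimated correlation), with cyb-3, a cyclin B gene, at 63 ± 5.32 against 424 ± 21.7 CPM and the ribonucleotide reductase gene rnr-2 at 79.9 ± 5.93 against 312 ± 27.7. Of 25 germline genes, 16 were lower and 2 higher (17 and 2 adjusted over the list alone, camera adjusted p = 0.00178, and adjusted p = 0.619 with an estimated correlation). Body wall muscle genes were lower in 24 of 27 cases (25 adjusted over the list alone, median -1.84, camera adjusted p = 1.05e-21, and adjusted p = 0.199 with an estimated correlation). The member unc-87 stood at 111 ± 14.3 against 801 ± 66.4 CPM. In the pharynx, 9 of 18 muscle genes were lower and 2 higher (9 and 3 adjusted over the list alone, camera adjusted p = 7.76e-07, and adjusted p = 0.203 with an estimated correlation), led by the pharyngeal myosins myo-1 at 13.3 ± 1.92 against 299 ± 11.9 CPM and myo-2 at 7.91 ± 1.77 against 270 ± 8.5. Pharyngeal gland genes were lower in 6 of 11 cases and higher in 1 (8 and 1 adjusted over the list alone, camera adjusted p = 0.000801, and adjusted p = 0.203 with an estimated correlation). The member phat-4 stood at 1.51 ± 0.328 against 56.3 ± 3.78 CPM.

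Yolk transcripts were lower in the elt-7 strain than in the control strain at 12 h. All 6 vitellogenin genes were lower (6 adjusted over the list alone, camera adjusted p = 0.00462, and adjusted p = 0.444 with an estimated correlation), vit-3 standing at 6.47 ± 3.78 against 2500 ± 415 CPM and vit-2 at 1060 ± 311 against 11800 ± 764. The genes ule-2, ule-3 and ule-4, named for uterine lumen expression, stood at 0.222 ± 0.0969, 0.771 ± 0.301 and 2.09 ± 0.304 CPM against 105 ± 7.73, 323 ± 13 and 472 ± 39.1. The list of somatic gonad, uterus and vulva was split, with 10 of 20 genes higher and 7 lower (10 and 7 adjusted over the list alone, median 0.54, camera adjusted p = 0.405). Y57G11B.5 stood at 0.291 ± 0.115 against 144 ± 23.4 CPM. Brush border genes were now higher in 6 of 11 cases (6 adjusted over the list alone, camera adjusted p = 0.012, and adjusted p = 0.463 with an estimated correlation), with ifo-1, an organizer of gut intermediate filaments, at 298 ± 13.6 against 82.6 ± 3.64 CPM and eps-8 at 161 ± 6.73 against 64 ± 0.512. Digestive enzyme genes were lower in 14 of 32 cases and higher in 4 (16 and 4 adjusted over the list alone, camera adjusted p = 0.00861, and adjusted p = 0.485 with an estimated correlation).

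In the lists of the pathogen response, the endoplasmic reticulum response, immune effectors, autophagy and moulting, more genes were called higher than lower at 12 h. In the intracellular pathogen response 14 of 20 genes were higher (14 adjusted over the list alone, median 5.07, camera adjusted p = 1.36e-11, and adjusted p = 0.267 with an estimated correlation), F26F2.1 standing at 82.9 ± 16.9 against 0.773 ± 0.0587 CPM. In the endoplasmic reticulum response 16 of 20 genes were higher (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000142, and adjusted p = 0.444 with an estimated correlation). The calreticulin gene crt-1 stood at 2850 ± 152 against 1290 ± 64.7 CPM. Of 33 immune effectors, 13 were higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.0194, and adjusted p = 0.631 with an estimated correlation). The lysozyme gene lys-3 stood at 113 ± 13 against 1.39 ± 0.419 CPM. Of 32 autophagy genes, 12 were higher and 2 lower (12 and 2 adjusted over the list alone, camera adjusted p = 0.00976, and adjusted p = 0.627 with an estimated correlation). The member sqst-1 stood at 811 ± 87.9 against 114 ± 11.8 CPM. Moulting genes were higher in 16 of 25 cases and lower in 5 (17 and 5 adjusted over the list alone, median 1.28, camera adjusted p = 0.000539, and adjusted p = 0.498 with an estimated correlation). The difference for the matrix gene noah-1 was 3.2 (log2). The lectin clec-45 stood at 313 ± 39.8 against 0.235 ± 0.0537 CPM, the chitinase-like chil-18 at 245 ± 65.5 against 0.23 ± 0.0782, pals-11 at 62.6 ± 6.41 against 0.0536 ± 0.00609 and scl-12 at 39.8 ± 7.24 against 0.0249 ± 0.0235. Without replicate 2 of the control strain at 0 h the calls for chil-18 (adjusted p = 0.125, range over all alternatives 2.78e-16 to 0.125), pals-11 (adjusted p = 1, range 5e-15 to 1) and scl-12 (adjusted p = 0.0635, range 8.36e-14 to 0.0635) were lost, with log2 differences of 9.15, 6.16 and 9.09 in that fit. In all, 4579 genes were higher and 4679 lower; upper-quartile factors moved the median of all genes from 0.10 to 0.24.

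At 30 h transcripts of sperm and of the larval moult, which fell in the control strain, were higher in the elt-7 strain. All 31 major sperm protein genes and 27 of 28 other sperm genes were higher (31, and 27 higher with 1 lower, adjusted over the list alone), with medians of 5.61 and 5.36. Their camera calls had adjusted p = 3.25e-14 and 1.58e-15, and adjusted p = 0.437 and 0.411 with an estimated correlation. The sperm gene msp-142 stood at 110 ± 14.4 against 2.44 ± 1.47 CPM and fer-1 at 54.7 ± 2.52 against 2.7 ± 0.195. Moulting genes were higher in 22 of 25 cases and lower in 1 (22 and 1 adjusted over the list alone, median 2.34, camera adjusted p = 6.76e-06, and adjusted p = 0.436 with an estimated correlation), qua-1 standing at 181 ± 31 against 10.4 ± 2.52 CPM and lin-42 at 96.3 ± 15.6 against 6.02 ± 0.861. Of 36 cuticle collagens, 25 were higher and 7 lower (25 and 7 adjusted over the list alone, camera adjusted p = 0.000683, and adjusted p = 0.546 with an estimated correlation). The member dpy-5 stood at 454 ± 87.7 against 6.23 ± 5.91 CPM and dpy-14 lower, at 2.33 ± 0.376 against 154 ± 80.1. Pharyngeal cuticle genes were higher in 17 of 20 cases and lower in 1 (17 and 2 adjusted over the list alone, median 4.71, camera adjusted p = 2.55e-05, and adjusted p = 0.444 with an estimated correlation). The member abu-10 stood at 55.2 ± 0.374 against 0.567 ± 0.476 CPM. Brush border genes were higher in 9 of 11 cases (9 adjusted over the list alone, camera adjusted p = 0.00467, and adjusted p = 0.436 with an estimated correlation). Their median was 1.53, whereas their median change from 0 h in the control strain was -2.3, so this need not be a rise from 0 h. The intermediate filament gene ifp-1 stood at 47.2 ± 2.68 against 6.08 ± 1.69 CPM.

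Oocyte, cell-cycle and yolk genes were lower at 30 h, relative to the control strain and to 0 h. From 0 h these lists rose in the control strain by medians of 5.31, 2.09 and 8.2. A smaller rise in the elt-7 strain would also give lower differences, so these need not be a fall. All 24 oocyte genes (median -2.36) and 27 of 28 replication and cell-cycle genes (median -1.30) were lower, 24 and 27 adjusted over the list alone. Their camera calls had adjusted p = 2.14e-06 and 1.93e-10, and adjusted p = 0.546 and 0.435 with an estimated correlation. Of 25 germline genes, 16 were lower and 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 0.0202, and adjusted p = 0.651 with an estimated correlation). The germline Notch receptor gene glp-1 stood at 91.1 ± 9.41 against 215 ± 25.7 CPM. Zygotic genes were lower in 10 of 20 cases (8 adjusted over the list alone, median -2.35, or -1.81 with groups at 0 set to 3 counts, camera adjusted p = 0.0942). The homeobox gene ceh-36 stood at 0.193 ± 0.0713 against 5.93 ± 1.13 CPM. All 6 vitellogenin genes were lower (6 adjusted over the list alone, camera adjusted p = 0.0683), vit-3 at 4.42 ± 0.908 against 3540 ± 2100 CPM; ule-1 stood at 0.0873 ± 0.019 against 132 ± 11.7 and the collagen col-135 at 0.0405 ± 0.00936 against 150 ± 27. Of 32 digestive enzyme genes, 21 were lower and 3 higher (21 and 3 adjusted over the list alone, camera adjusted p = 0.00468, and adjusted p = 0.444 with an estimated correlation). The cathepsin D gene asp-4 stood at 113 ± 9.1 against 366 ± 27.3 CPM. Autophagy genes were lower in 18 of 32 cases and higher in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 0.0223, and adjusted p = 0.631 with an estimated correlation). The member epg-2 stood at 18.5 ± 2.52 against 165 ± 34.3 CPM. In lipid synthesis 12 of 18 genes were lower and 2 higher (12 and 2 adjusted over the list alone, camera adjusted p = 0.337). The desaturase gene fat-7 stood at 1.07 ± 0.185 against 127 ± 52 CPM. In the list of somatic gonad, uterus and vulva 8 of 20 genes were higher and 3 lower (8 and 2 adjusted over the list alone, median 0.36, camera adjusted p = 0.217).

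In the intracellular pathogen response 10 of 20 genes were higher at 30 h and 1 lower (10 and 1 adjusted over the list alone, median 2.69, camera adjusted p = 0.0322, and adjusted p = 0.651 with an estimated correlation). The member pals-1 stood at 20.9 ± 2.04 against 0.966 ± 0.0492 CPM. Of 33 immune effectors, 18 were higher and 4 lower (18 and 4 adjusted over the list alone, camera adjusted p = 0.058). The antimicrobial peptide gene nlp-34 stood at 115 ± 3.18 against 4.32 ± 1.64 CPM. Neuronal genes were higher in 18 of 25 cases and lower in 3 (18 and 3 adjusted over the list alone, camera adjusted p = 0.0654). Their median was 0.77, whereas their median change from 0 h in the control strain was -1.23, so this too need not be a rise. Heat shock genes were lower in 11 of 24 cases (11 adjusted over the list alone, camera adjusted p = 0.0573). The member hsp-12.6 stood at 0.401 ± 0.0272 against 14.1 ± 5.72 CPM. The highest single differences included lips-6 at 27.9 ± 10.1 against 0.305 ± 0.203 CPM, clec-174 at 64.3 ± 13.7 against 0.184 ± 0.104, F20B10.3 at 27.4 ± 5.35 against 0.207 ± 0.0539 and pals-11 at 11.7 ± 1.28 against 0.0464 ± 0.0468. The call for pals-11 was lost without replicate 2 of the control strain at 0 h (log2 4.02, adjusted p = 0.975, range over all alternatives 9.39e-12 to 0.975). In all, 5269 genes were higher and 6610 lower. The share of higher calls was 44.4%, against 58.6% with upper-quartile factors, which moved the median of all genes from -0.13 to 0.23.

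**Figure D2:**
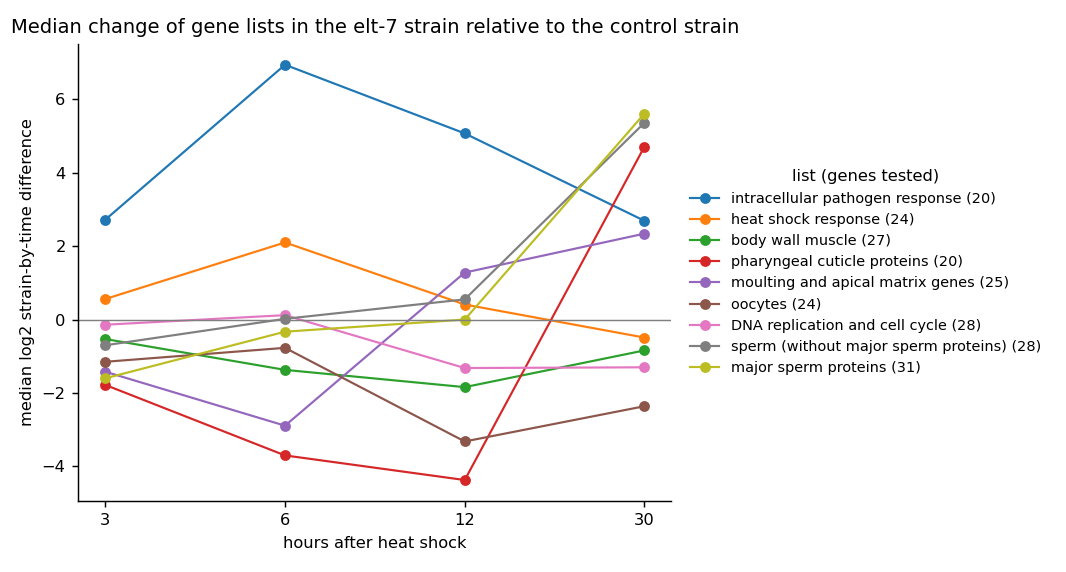
Median log2 strain-by-time difference (vertical axis) of 9 gene lists against hours after heat shock. There is 1 point per list and time, with the number of genes tested in brackets. Values above 0 mean a change from 0 h that was more upward or less downward in the elt-7 strain than in the control strain. The intracellular pathogen response peaked at 6.94 at 6 h, and the sperm lists stood at 5.36 and 5.61 at 30 h; the sperm list's median of 0.02 at 6 h turned to -0.02 on the TPM scale.

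**Figure D3:**
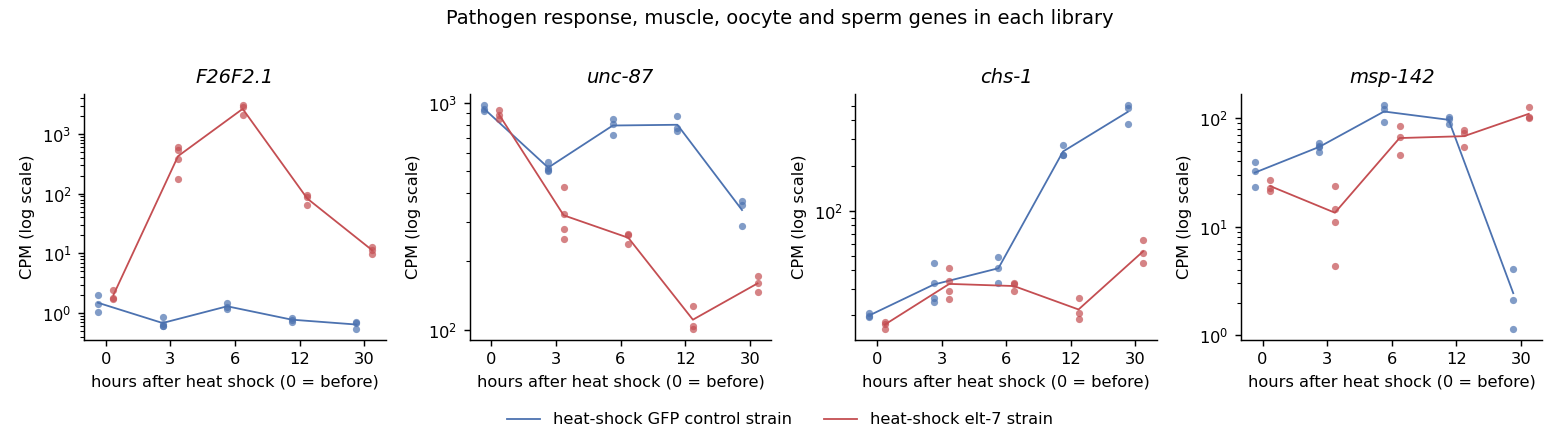
Levels of F26F2.1, unc-87, chs-1 and msp-142 in CPM (log axis) against hours after heat shock, with 1 point per library and lines through group means (red, elt-7 strain, blue, control strain). Transcripts of msp-142 stood at 110 CPM in the elt-7 strain and 2.44 in the control strain at 30 h.

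The elt-7 strain was also set directly against the control strain at each later time. Between the strains 7039 genes were higher and 6248 lower in the elt-7 strain at 3 h, 7258 and 5860 at 6 h, 7076 and 5587 at 12 h, and 7074 and 7360 at 30 h. Of the genes called in the strain-by-time difference, 95.1%, 96.2%, 95.7% and 96.5% at 3, 6, 12 and 30 h were also called with the same sign in the strain difference, which uses the same libraries of that time. Genes called higher at all 4 later times but not at 0 h numbered 1405, and 1062 were lower. Independent times would give 376 and 221, but the same strains are compared each time, so any lasting difference between them also gives an excess. Genes not called at 0 h may still have differed then. Transcripts of elt-2 and ifb-2 were higher in the elt-7 strain at every time, elt-2 by 1.15 (log2) at 0 h and by 3.32, 2.39, 2.72 and 1.95 at 3, 6, 12 and 30 h. The collagen gene rol-6 was higher at 3 h by 0.59 (adjusted p = 0.0151) and lower at 6 h by -0.63 (adjusted p = 0.0243). The first call was lost without replicate 3 of the elt-7 strain at 3 h (adjusted p = 0.177), on the TPM scale (0.191), with effective lengths (0.0683) and with only the groups compared (0.0946), over a range of 0.000797 to 0.191. The other was lost without replicate 2 or 3 of the elt-7 strain (0.0689 and 0.0545) or replicate 2 of the control strain (0.0512) at 6 h, over a range of 3.86e-05 to 0.0689. Of the calls at 3 h, 53% were higher, against 38.8% on the TPM scale, which moved the median of all genes from 0.04 to -0.16; at 30 h upper-quartile factors moved it from 0.01 to 0.31.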

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

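The tests of the genes without reads at 3 h, of the elt-7 strain at 30 h and of the pathogen response were chosen only after the results were seen, and so were the split counts for the strain differences and control changes.

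In the groups of 4 libraries at 3 h, a library stood apart in 7 of 54 sets of values tested, where chance gives about 1 in 20, or 2.7. In 3 of the 7 a single library had reads, which sets it apart by construction, so an excess over chance is not shown by the other 4. In the elt-7 strain at 3 h, replicate 3 had 2650 CPM of elt-7 against 449 to 702 in the others and 694 CPM of hsp-16.2 against 260 to 306. In the control strain at 3 h, replicate 2 had 84 CPM of hsp-16.2 against 127 to 132. Replicate 1 had 174 CPM of the collagen col-19 against 21.7 to 46.6. In that group fbxa-28 had 0.0504 CPM in replicate 2, W07G4.1 had 0.0498 in replicate 4 and clec-121 had 0.0427 in replicate 1, with no reads in the others.

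The response to heat shock differed between the strains by the test of the difference itself, in 8467 genes at 3 h, 9063 at 6 h, 9258 at 12 h and 11879 at 30 h. For these, 25 splits each were drawn of 700 possible at 3 h and 200 at the other times. The real split was the 1 with the most genes at 3 h (highest other 68), which argues against chance in how these libraries were grouped. No other split drawn kept the true strains at 3 h, but only 20 of the 700 possible do, a share of 0.029, against 20 of 200 (0.1) at the other times. At 6 h, 5 of 25 splits gave as many genes, with 11098 the highest other, so chance is not excluded by this count. The 4 others that reached it all kept the true strains at 6 h and mixed libraries of 0 h, and splits that mixed strains at 6 h gave at most 35 genes. At 12 and 30 h the real split also gave the most genes, but the highest others (9233 and 11846) came from the 1 and 2 splits drawn that kept the true strains at the later time. The share there depends on which splits were drawn, so chance is not excluded at 12 and 30 h by this count either. Splits that mixed the strains at the later time gave at most 10 and 24 genes. For the strain difference at 3 h (13287 genes, highest other 4986) and the control change at 3 h (7760, highest other 4789), 1 of 35 splits gave as many, which argues against chance in how these libraries were grouped. Splits of libraries cannot exclude a chance difference between cultures, since the labels do not say whether replicates came from separate ones. In the control change at 3 h they also cannot separate time from the other length correction of the 3 h libraries. The other strain differences and control changes have 10 splits, too few for a share under 0.05. Their real values and highest others were 887 and 0, 13118 and 0, 12663 and 0, and 14434 and 12 for the strain differences at 0, 6, 12 and 30 h. For the control changes at 6, 12 and 30 h they were 6312 and 0, 10999 and 0, and 13895 and 2.

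At 3 h, 8 genes that averaged over 1 CPM elsewhere had no reads in any of the 8 libraries. The same count was 50 at 0 h, over 6 libraries, and 0, 1 and 1 at 6, 12 and 30 h. A candidate explanation is that reads of near-identical copies were given to 1 copy in the libraries with the other length correction. Copies were taken by a shared symbol stem, without comparing sequences, and the one that rose most in the control strain was chosen. In 6 of the 8, which share 4 separate copies, that copy rose at 3 h, by 3-fold for his-9 to 36.1-fold for the heat-shock gene hsp-16.1. The 6 include the F45D11.16 genes, matched to F45D11.14 only by a sequence name without its last number. Such a match, also used for T28C6.11, need not be a copy. Of genes with at least 1 CPM in the control strain at 0, 3 or 6 h, taken singly, 1.8% rose 2-fold, a limit chosen after these values were seen. Because the copy was the highest of its stem, the 1.8% is not a like comparison. For those 6 the sum over copies at 3 h was not below the lower of 0 and 6 h, as for pud-1.1 and pud-1.2 (219, 823 and 761 CPM at 0, 3 and 6 h). They were picked because the copy rose, which largely fixes that outcome, so loss of the transcripts stays open. For T28C6.11 the sum with T28C6.10, which did not rise, was 11, 1.67 and 9.86 CPM at 0, 3 and 6 h. For the remaining 2, nola-3 and T28C6.11, loss and quantification cannot be told apart either, because all libraries of 3 h carry that correction.

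At 30 h the elt-7 strain held more moulting and sperm transcripts and fewer oocyte transcripts than the control strain. Scaling between libraries is argued against, since a factor per library moves all genes alike, whereas each of these lists, and the list of DNA replication and cell cycle, lay at least 1.16 (log2) from the median of all genes, some above and some below it. Other size factors cannot change that distance. Slowed development in the elt-7 strain may account for it: over 18640 genes, which are not independent replicates, its change at 30 h correlated more with the control strain's change at 12 h (Pearson r 0.57, 0.55 to 0.58 leaving out 1 library) than with that at 30 h (0.35, 0.33 to 0.37). By this measure no delay shows in its change at 12 h, nearest the control strain's at 12 h (0.41, against 0.3 at 3 h and 0.22 at 6 h), or at 6 h, also nearest that at 12 h (0.31, against 0.23 at 6 h). The lists already differed at 12 h, with medians of 1.28 for moulting, -3.32 for oocytes and -1.32 for replication and cell cycle, so the time at which a delay would begin stays open. A loss of oocytes or germ cells without delay was not tested and stays open, as does a direct action of ELT-7 on these genes. The oocyte list rose from 0 h in the control strain by a median of 5.31, against a median difference of -2.36 at 30 h. Oocyte transcripts need not have fallen from 0 h in the elt-7 strain.

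Genes of the intracellular pathogen response were higher in the elt-7 strain, most at 6 h. Heat shock by itself is argued against, with 0 list members higher in the control strain at 6 h and 3 at 3 h (edgeR, 20 tested). The difference present at 0 h (median 0.82), if it stayed constant, is argued against as the whole cause, since the strain-by-time median was 6.94 at 6 h. Subtracting 0 h cannot exclude another difference between the strains, apart from heat-shock elt-7, that grows with time or reacts to heat. That was not tested. A stronger heat shock in the elt-7 strain cannot be told apart from an action of ELT-7: 19 of 24 heat shock genes were higher there at 6 h, and the strains had a single heat dose. The induction of ELT-7 therefore stays a hypothesis for this list.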

How the results depend on the processing

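The alternatives without the 3 h libraries, without the genes at 0 reads in all of them and, for gene lists only, without replicate 3 of the elt-7 strain at 3 h were chosen only after the data were examined, and the others before. The search for GATA motifs upstream of called genes was not run, since no genome sequence was used here. All 13 counts of called genes stayed within 1.5 times under RLE size factors, upper-quartile factors, both filters, DESeq2, limma-trend on TPM, the effective length offset and without the genes at 0 at 3 h. With the fold threshold of 2, which is stricter by construction, the counts were 428, 7509, 7550, 6982 and 8811 for the strain differences at 0, 3, 6, 12 and 30 h. They were 5454, 5776, 5378 and 7717 for the strain-by-time differences at 3, 6, 12 and 30 h, and 2446, 2704 and 5118 for the control changes at 3, 6 and 12 h. The strain difference at 0 h was 2220 without the 3 h libraries (885 shared with the 887) and 2884 with only the 6 libraries compared (771 shared), and the cause was not tested. All groups share 1 estimate of the spread per gene. The lowest correlation of replicate pairs in the elt-7 strain was 0.886 at 3 h and 0.992 at 0 h. With a shared spread, p-values may be too small at 3 h and too large at 0 h. Leaving out 1 replicate gave 400 to 695 there, with fewer samples. The lowest values came without replicate 3 (400) or 1 (456) of the control strain and replicate 1 (449) or 2 (486) of the elt-7 strain. No call of a named gene changed direction under any alternative. For lists, the median changed sign in 57 combinations of list, comparison and setting, and the majority of calls in 33, over 21 lists, and the cause was not tested. The heat shock median of the control change at 3 h, -0.13, was 0.23 on the TPM scale.

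Of 308 results for genes admitted by the rule, 274 kept their side of the threshold in every alternative and 284 without the fold threshold. The fold threshold ended 12 calls, and leaving out 1 library ended a call in 35 fits and kept the result in 3391. Of 252 list results, 71 were the same in every alternative and 185 when the estimated correlation was left aside; that estimate ended 128 calls, fry ended 10 and added 52, and RLE size factors ended 1 and added 2. At the depth and replicate number of these libraries, neither of which was varied, 46% of 2-fold and 88% of 4-fold changes were recovered in the simulation of the strain-by-time difference at 6 h. Few genes changed in that simulation, so these shares need not hold where many genes change.

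Replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.33 to 0.31 over 16 pairs of samples (11911 genes), 6 of them over 0.1, and the own number was best in 7. With the replicate number as a block the counts were 963, 13347, 13279, 12779 and 14542 for the strain differences, 8672, 9184, 9408 and 12009 for the strain-by-time differences and 7573, 6442, 11168 and 13978 for the control changes. With the block by time they were 669, 12998, 12778, 12359 and 14307, and 8094, 8641, 8838 and 11677. No call of a named gene changed under the block (308 results) or the block by time (274, control changes not included); among lists the first ended 5 calls and added 2, and the other ended 1 and added 12.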

Other observations

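All tests in this part were chosen only after results were seen. Many genes for chemoreceptors, the receptors by which nematode sensory neurons detect odours and tastes, had transcripts in the elt-7 strain soon after heat shock. Of 759 tested genes of 20 chemoreceptor families, 321 averaged at least 1 CPM in the elt-7 strain at 3 h and 37 in the control strain. The numbers were 30 and 23 at 0 h, 176 and 28 at 6 h, 72 and 24 at 12 h, and 53 and 20 at 30 h. In the strain-by-time difference 249 were higher and 26 lower at 3 h (edgeR), 190 and 41 at 6 h, 96 and 40 at 12 h, and 89 and 38 at 30 h. The higher ones were 32.8%, 25% and 11.7% of the chemoreceptors at 3, 6 and 30 h, against 20.9%, 23.4% and 28.3% of all genes. At 12 h 96 of 759 were higher, against 24.6% of all genes, so at 12 and 30 h chemoreceptors were called higher less often than genes in general. The median of the 759 was 0.759 CPM in the elt-7 strain at 3 h and 0.0499 to 0.0815 in the control groups. With so few control reads, many could pass the filter on low counts largely through the elt-7 strain after heat shock. The excess of higher calls over all genes at 3 h may thus be partly built in. Under upper-quartile factors, RLE size factors and effective lengths, higher calls outnumbered lower ones at each time, with 130 and 24 at 30 h under the first. Without replicate 3 of the elt-7 strain at 3 h, 246 were higher and 28 lower. More genes were detected in general: at an equal depth of 16 x 1e6 reads, 16304 ± 185 genes (SD, n = 4) had at least 10 reads in the elt-7 strain at 3 h and 15354 ± 133 in the control strain. At 30 h these were 15498 ± 22 and 13763 ± 221 (n = 3).

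Gene families defined by shared symbols were tested for enrichment among genes that were called and changed at least 8-fold in the strain-by-time difference (Fisher's exact test, one-sided, Benjamini-Hochberg over 1376 tests of 172 families, each with at least 10 tested genes), and 77 tests passed, in 44 families. Members of a family are not independent, so these p-values are too small. In families with few control reads, the filter on low counts also favours genes with reads in the elt-7 strain after heat shock. At 3 h the str chemoreceptors led the higher genes, with 39 of 114 (adjusted p = 1.1e-18), then by adjusted p the cytochrome P450 family cyp (19 of 74, 8.84e-07), the chemoreceptors srz (13 of 34, 8.84e-07) and the ugt family (18 of 67, 9.15e-07). Among the higher genes at 6 h the lowest adjusted p were those of pals (24 of 38, adjusted p = 1.91e-19), str (29 of 114, 7.01e-11) and the chitinase-like chil genes (13 of 26, 1.1e-08). At 12 h collagens of the col family were among the lower genes (35 of 152, adjusted p = 1.02e-17), as were the fipr genes (15 of 22, 1.17e-15). At 30 h 74 of 152 col genes were among the higher (adjusted p = 7.48e-26) and 12 among the lower (0.0323), with 32 of 100 F-box fbxb genes among the lower (2.17e-22).

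Of 1238 tested genes under 0.2 CPM on average in every control group and in the elt-7 strain at 0 h, 133 averaged at least 5 CPM in the elt-7 strain at 3 h, 120 at 6 h, 58 at 12 h and 16 at 30 h. In every replicate they did so in 72, 108, 51 and 14 cases. Over all times these were 179 genes, of which 42 were chemoreceptors, 9 were C-type lectins and 8 were pals genes. Chemoreceptors were 455 of the 1238, so their share among the 179 (23.5%) was below that among the 1238 (36.8%). The 1238 had passed the filter on low counts, which such genes could do largely through the elt-7 strain after heat shock. They are therefore not all near-silent genes, and both their number and the 36.8% depend on that filter. The polycystin-1 homologue gene lov-1, known from sensory neurons of males, stood at 0.08 CPM at 0 h, 78.54 at 3 h, 67.76 at 6 h, 7.62 at 12 h and 0.32 at 30 h in the elt-7 strain, and under 0.2 CPM on average in the control strain. Before heat shock, unc-119 stood at 250.6 CPM in the elt-7 strain and 14.53 in the control strain, and at 3 h at 1095 and 12.4. C39B10.7 stood at 67.72 and 1.583 CPM at 0 h and at 2196 and 1.532 at 3 h. The labels do not say whether a transgene of the elt-7 strain carries sequence of unc-119 or C39B10.7, so these need not be levels of the native genes.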
